A study of Mus musculus with 6 samples.

How the data were processed

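The series holds 6 circRNA libraries of mouse ovary, 3 of mice kept at normal pressure and 3 of mice kept in hypobaric hypoxia, all given as 1 batch in the labels. Per the labels' protocols, total RNA was extracted with TRIzol and treated with DNase I, ribosomal RNA was removed with a Ribo-off kit, linear RNA was digested with RNase R, and strand-specific libraries were sequenced on a DNBSEQ-G400 instrument. The submitters' processing notes name BWA, Bowtie2 and the mouse build GRCm38, without versions or roles. The circRNA caller, the annotation and the filters are not given in the sources used here.

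The deposited table holds RPM values, which the authors scaled so that each library sums to the same total, between 999996 and 1000027, over the listed circRNAs. The values are therefore relative abundances within the circRNA fraction, and total circRNA abundance, which had been planned as a result, could not be compared. All 6 columns of values were used. The IDs are numbers without coordinates or gene names, so planned tests on host genes and on gene lists were left out, and no annotation was joined. Of the listed circRNAs, 8483 were at 0 in all 6 libraries.

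In each library the RPM values were whole multiples of a fixed step, with 100% of the values above 0 within 0.05 of a whole number of reads when the smallest value is taken as 2 reads. The step, which is the RPM of 1 read, was 2.74, 6.61 and 2.71 in normal pressure replicates 1, 2 and 3 and 2.00, 1.90 and 2.05 in hypobaric hypoxia replicates 1, 2 and 3. No value of 1 read was listed. The smallest values above 0 were 5.48, 13.2, 5.42, 3.99, 3.80 and 4.11 RPM in the same order, so a circRNA listed at 0 can be present below this level. Reads without molecular identifiers are not independent molecules. The recovered reads were used for depth, for thinning and for alternatives, and the main test used the RPM values. Between replicates the chi-square per degree of freedom was 2.74 to 3.56 over circRNAs with at least 20 reads, and no pair stood apart from the other pairs of its group. It takes reads as independent, so it does not exclude repeats of 1 RNA sample, and each library was counted as 1 replicate, as the labels give them.

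Abundance was compared on log2(RPM + 4.765), the pseudocount being the median over libraries of the smallest RPM above 0, so fold changes of scarce circRNAs are understated on this scale. CircRNAs above 0 in at least 3 of the 6 libraries were tested with limma 3.58.1 in R 4.3.3, with an intensity trend and robust empirical Bayes variances, group as the only term, two-sided, with Benjamini-Hochberg adjustment at 0.05. The test was tried on simulated reads with 200 changed circRNAs per run in 10 runs at the depths of the real libraries, where 5.10% of the calls were false. In simulated libraries with no change the mean number of calls was 0.5. The simulation gave circRNAs of like abundance the same spread, as the intensity trend assumes. It therefore does not show how many calls are false where their spreads differ. Numbers of circRNAs per library were compared with exact two-sided permutation tests of the mean in scipy 1.17.1, whose smallest p with 3 against 3 is 0.1.

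For equal depth, reads were drawn at random so that the reads kept, after removing circRNAs left with fewer than 2, numbered 151364 in each library, the depth of the shallowest. Each draw was repeated 20 times and averaged, except that calls at equal depth are those of the draw with the median number of calls. The share of reads kept was 100% in normal pressure replicate 2 and between 29.8% and 42.6% in the other libraries. A second set of draws brought the 5 deeper libraries to 365070 reads. Draws of these libraries in couples of reads were repeated 10 times.

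The rule for circRNAs described one by one was fixed before the data were examined. It takes the 10 largest rises and 10 largest falls among called circRNAs with groups that do not overlap, and the 8 of highest mean RPM. Because the IDs have no gene names, only 4 are printed, chosen after the values were seen as the largest change and the smallest p of the 10 in each direction. The largest fall also has the smallest p, and there the next smallest was taken. The alternatives fixed before the data were examined changed the pseudocount, the filter, the scaling between libraries, the variance model, library weights, the replicate number as a block, the libraries included, the threshold and, for the number of circRNAs detected, the read minimum and depth, with the read minimum also for circRNAs seen in one group only. Thinning for the comparison of abundance and for the circRNAs seen in one group only, precision weights on the recovered reads (limma voom) and leaving out libraries in the counts of circRNAs seen in one group only, in the values at equal depth and in the correlations between libraries were chosen after seeing the data. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used for thinning and counting.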

Results

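Circular RNAs (circRNAs), closed RNA molecules formed when the end of an exon is joined back to the start of the same or an upstream exon, were sequenced from ovaries of female C57BL/6J mice, an inbred laboratory strain. One group lived for 15 days at the pressure of Lanzhou, China (83.56 kPa, oxygen 17.8 kPa), and the other for 15 days in a hypobaric chamber (43.12 kPa, oxygen 8.1 kPa). The chamber setting corresponds to 6500 m by the titles and the design text, and to 5000 m by the sample descriptions. Each group had 15 mice and gave 3 libraries. The labels do not say whether a library holds RNA of 1 mouse or of a pool, so the spread between libraries may be technical. For most circRNAs the limma p-values rest mainly on the spread pooled over circRNAs of like abundance, and little on their own spread. Before the exposure the mice were synchronized with levonorgestrel and ethinylestradiol, the hormones of a combined contraceptive. The labels name both hormones for both groups, and give their doses (0.1 and 0.02 mg/kg) for the hypobaric hypoxia group only.

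The table listed 57233 circRNAs by ID, with a relative abundance in RPM (reads scaled to a fixed total per library) for each library. It does not pair the IDs with genes or coordinates, so no host gene is given for any circRNA. A circRNA was seen (RPM above 0) in at least 1 library in 48750 cases, in at least 3 libraries in 15737 and in all 6 libraries in 6057. The 6057 circRNAs shared by all libraries held between 82.9% and 89.5% of the RPM of a library, and 26762 circRNAs were seen in 1 library. The reads behind the values, recovered from the steps between low RPM values, numbered 365070, 151364 and 369055 in normal pressure replicates 1, 2 and 3. In hypobaric hypoxia replicates 1, 2 and 3 they numbered 500927, 526621 and 487143, so each hypoxia library was deeper than each normal pressure library. Depth here means these circRNA reads, since the total reads sequenced per library are not given in the sources used here.

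**Figure D1:**
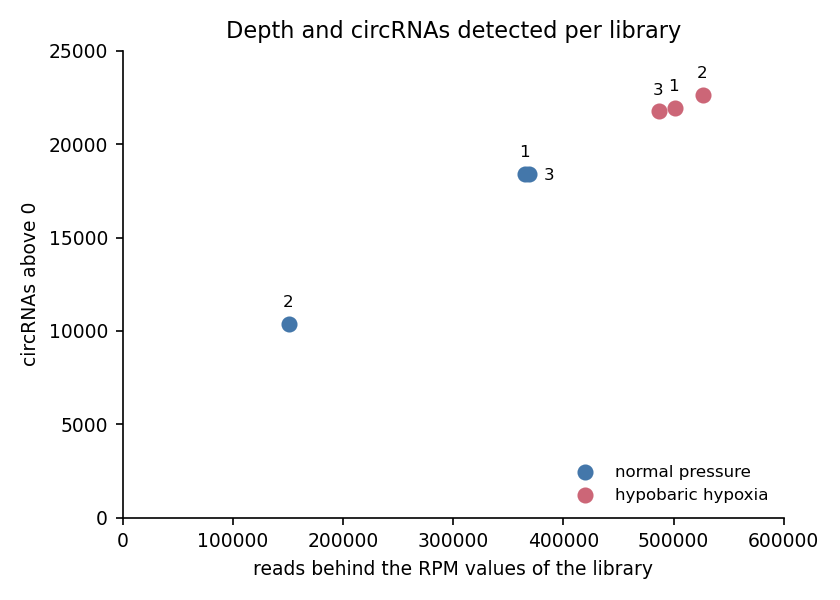
Reads behind the RPM values (horizontal axis) and number of circRNAs above 0 (vertical axis) in each of the 6 libraries, with the replicate number beside each point. The 3 hypobaric hypoxia libraries lie at the highest depth and number of circRNAs (21761 to 22628), and normal pressure replicate 2 at the lowest (10399).

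The main comparison addressed which circRNAs of the ovary differed in abundance after hypobaric hypoxia. Of 15737 circRNAs tested, 26 were higher and 38 were lower in hypobaric hypoxia than in normal pressure (limma, Benjamini-Hochberg adjusted p under 0.05). The 38 lower circRNAs had a median log2 fold change of -1.01 (range -3.70 to -0.43), and 20 of them changed by at least 2-fold. The 26 higher circRNAs had a median log2 fold change of 0.72 (range 0.26 to 2.74), and 7 of them changed by at least 2-fold. Together the 26 higher circRNAs held 2.43% ± 0.0556 of the RPM in normal pressure and 3.33% ± 0.199 in hypobaric hypoxia (SD, n = 3). The 38 lower circRNAs held 2.25% ± 0.153 in normal pressure and 1.31% ± 0.0885 in hypobaric hypoxia (SD, n = 3). These shares describe circRNAs selected on the same libraries.

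By log2 fold change with the pseudocount, the largest fall was that of novel_circ_041272, from 339 ± 147 RPM in normal pressure to 20.6 ± 6.36 RPM in hypobaric hypoxia (SD, n = 3). By the ratio of mean RPM it was not the largest, at 16.4 against up to 21.3 among the 10 largest falls. Its log2 fold change was -3.70 with a standard error of 0.33 (limma adjusted p = 2.46e-24), and it had the smallest p of all circRNAs tested. Without normal pressure replicate 3 its limma adjusted p was 0.023, and without an intensity trend and robust variances it was 0.159, above the threshold. The abundance of novel_circ_043894 fell from 236 ± 57.6 to 75.6 ± 20.0 RPM (SD, n = 3), a log2 fold change of -1.58 with a standard error of 0.27 (limma adjusted p = 2.02e-05). Without normal pressure replicate 3 its log2 fold change was -1.48 and the call was lost (limma adjusted p = 0.336). The remaining 8 of the 10 largest falls had log2 fold changes between -3.18 and -1.49.

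The abundance of novel_circ_023565 rose from 332 ± 24.5 RPM in normal pressure to 722 ± 54.0 RPM in hypobaric hypoxia (SD, n = 3), with a log2 fold change of 1.11 and a standard error of 0.16 (limma adjusted p = 2.88e-08). The largest rise was that of novel_circ_033284, from 6.21 ± 6.64 to 64.4 ± 36.4 RPM (SD, n = 3), with a log2 fold change of 2.74 and a standard error of 0.70 (limma adjusted p = 0.0289). It was listed at 0 in normal pressure replicate 1 and rested on 2 reads in each of the other normal pressure libraries, and 10 of 17 alternative settings ended its call, the 5 in which normal pressure replicate 1 or 3 or any hypoxia replicate was left out among them. The other 8 of the 10 largest rises had log2 fold changes between 0.92 and 1.99.

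**Figure D2:**
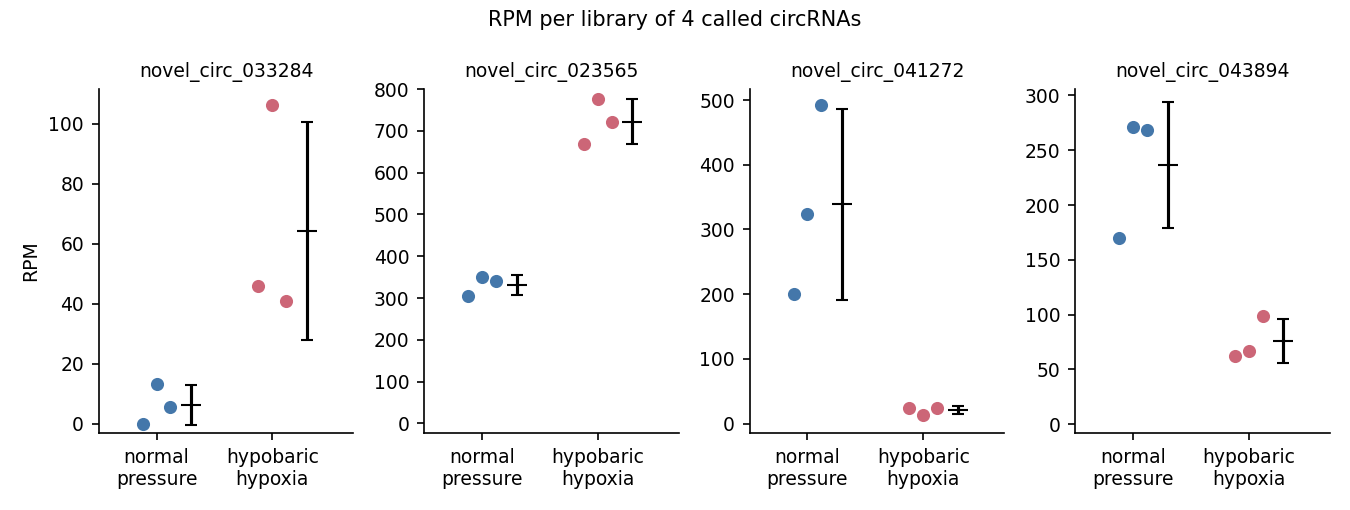
RPM of 4 called circRNAs in each library (points) of normal pressure and hypobaric hypoxia, with the mean and SD of the 3 libraries of a group (black bars) and a separate linear axis for each circRNA. The 2 groups do not overlap for any of the 4, and the SD of novel_circ_033284 in normal pressure is larger than its mean.

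The called circRNAs were mostly abundant ones. Their median abundance was 316 RPM, against 14.8 RPM over all circRNAs tested, and 23 of the higher and 31 of the lower ones were among the 1573 most abundant circRNAs tested. Of the 64, 59 were seen in all 6 libraries and 63 had groups that did not overlap. Among all circRNAs tested, 14.0% had groups that did not overlap, where chance gives 10%. These 2199 circRNAs include the 655 seen in all libraries of one group and in none of the other. Such circRNAs cannot overlap, and their number fell at equal depth, so the share does not measure change in abundance alone. In simulated libraries of the same depths, the changed circRNAs were drawn from those above the median abundance of the circRNAs tested. There the test found 20% of circRNAs raised 2-fold, 10% of those lowered 2-fold, 71.4% of those raised 4-fold and 25.2% of those lowered 4-fold. Changes of this size in circRNAs that were not called are therefore not excluded. For circRNAs below the median abundance the share found was not simulated.

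Of the 8 most abundant circRNAs, 2 differed between the groups. The most abundant one had 14738 ± 2389 RPM in normal pressure and 11794 ± 982 RPM in hypobaric hypoxia (SD, n = 3), with a log2 fold change of -0.31 (95% interval -0.69 to 0.06). Those ranked 5 and 7 were called, each with a log2 fold change of 0.26 (limma adjusted p = 0.00596 and 0.00873). The circRNA ranked 6 had the widest interval of the 8, -1.27 to 0.03 around a log2 fold change of -0.62.

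**Figure D3:**
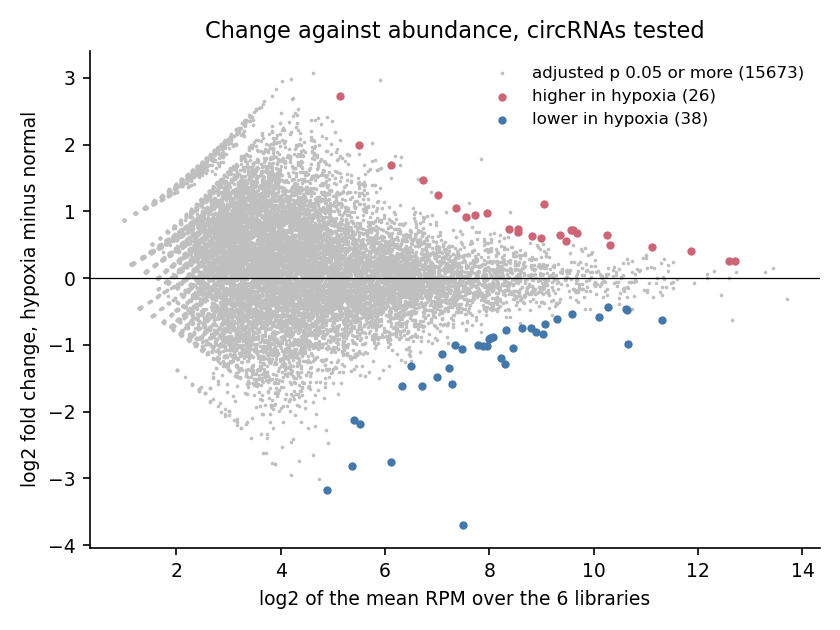
Log2 fold change, hypobaric hypoxia minus normal pressure (vertical axis), against the log2 of the mean RPM over the 6 libraries (horizontal axis) for the 15737 circRNAs tested. The 26 circRNAs called higher and the 38 called lower are coloured, and most of them lie among the abundant circRNAs.

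The split of the calls moved with the scaling between libraries. After each library was centred on its median over the circRNAs seen in all 6 libraries, 37 circRNAs were called higher and 22 lower. The number of calls fell to 6, 4, 21 and 27 without normal pressure replicate 1 or 3 and hypobaric hypoxia replicate 2 or 3, and to 41 without hypobaric hypoxia replicate 1, to 27 with a pseudocount of 1.19 RPM and to 0 in limma without an intensity trend and robust variances, where 1408 circRNAs had an unadjusted p under 0.05. In the main test 1354 circRNAs had an unadjusted p under 0.05, where chance gives 787, and 906 of these were higher and 448 lower. Libraries simulated at the same depths with no circRNA changed gave a like ratio, with 547.5 higher and 276.3 lower on average over 10 runs and a median log2 fold change of 0.09. The median log2 fold change of all circRNAs tested was 0.18, -0.07 among those seen in all 6 libraries and 0.43 among the rest. With all libraries thinned to the depth of the shallowest, the median was 0.05, and on average 449 circRNAs were higher and 351 lower at an unadjusted p under 0.05.

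A further comparison addressed whether the number of circRNAs seen differed between the groups. As deposited, 22110 ± 458 circRNAs were seen in a hypobaric hypoxia library and 15741 ± 4627 in a normal pressure library (SD, n = 3), a difference of 6369 (exact permutation test, two-sided, p = 0.1, the smallest p that 3 against 3 libraries allow). Counting only circRNAs above 4 reads, the difference was 3907. After thinning to equal depth the numbers were 12208 ± 47.1 and 11399 ± 866 (SD, n = 3), a difference of 810 (exact permutation test, two-sided, p = 0.1). Without normal pressure replicate 2, the shallowest library, the difference was 3698 as deposited and 310 at equal depth. At the depth of the next shallowest library, 18397 and 18324 circRNAs were seen in normal pressure replicates 1 and 3, and between 18890 and 18943 in the hypobaric hypoxia libraries. With reads drawn in couples instead of singly, in case they were counted in couples, the numbers were 18397 and 18364 against 19686 to 19878. Drawing couples keeps more scarce circRNAs in a library that loses reads.

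CircRNAs seen in all 3 libraries of one group and in none of the other were also counted. As deposited, 605 were seen in hypobaric hypoxia only and 50 in normal pressure only, while the 18 mixed sets of 3 libraries gave between 33 and 380. None of the 605 and none of the 50 was called by limma in the comparison of abundance. Their means over the 3 libraries were at most 36.8 RPM. There, standard errors are large next to the log2 fold changes that the pseudocount allows, so few could have been called. They were scarce, with a median over circRNAs of 5 reads per library for the 605 and 3.67 for the 50, and held 0.652% and 0.0788% of the RPM of the libraries they were seen in. At equal depth the numbers were 191 ± 14.6 in hypobaric hypoxia only and 82.6 ± 6.14 in normal pressure only (SD over 20 draws), against 76.8 to 167.5 in mixed sets. The 605 became 1157, 762 and 1388 without normal pressure replicate 1, 2 or 3, and 1449, 1387 and 1522 without hypobaric hypoxia replicate 1, 2 or 3, and the 50 became between 83 and 377, the highest without normal pressure replicate 2. The condition then covers 5 libraries instead of 6.

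**Figure D4:**
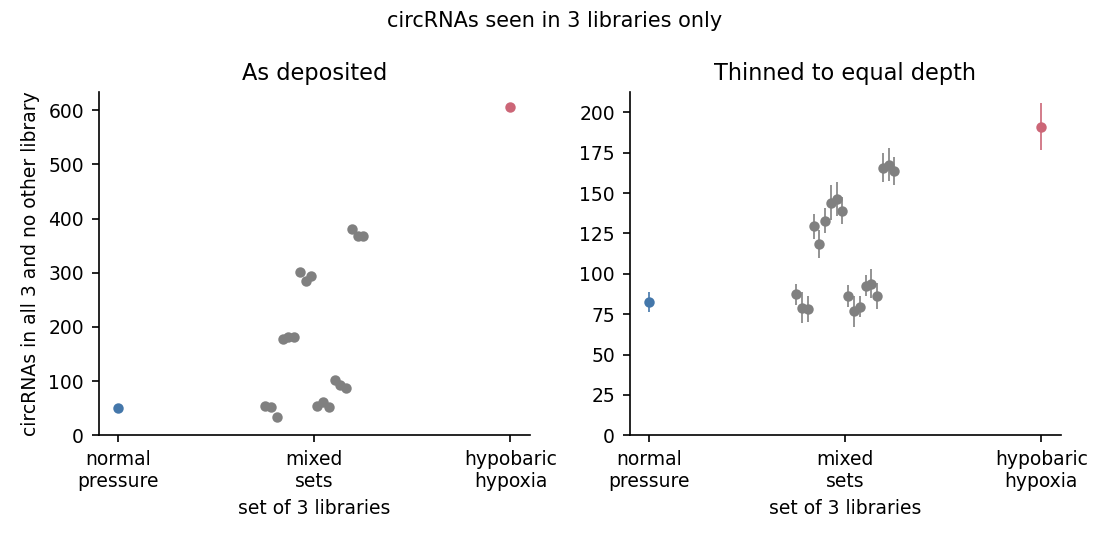
Number of circRNAs seen in all 3 libraries of a set and in none of the other 3, for the 2 groups and the 18 mixed sets of 3 libraries, as deposited and after thinning to equal depth (points: mean, bars: SD over 20 draws). The hypobaric hypoxia set is highest in both panels, at 605 and 191, and the highest mixed sets reach 380 and 167.5.

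Libraries were also compared by the Pearson correlation of log2 abundance across the 2000 most abundant circRNAs, which are not independent replicates. It was 0.948 to 0.949 between hypobaric hypoxia libraries, 0.880 to 0.923 between normal pressure libraries and 0.867 to 0.924 between libraries of different groups. Normal pressure replicate 2 stood apart, and without it the correlation was 0.923 between the normal pressure libraries and 0.904 to 0.924 between groups. At equal depth the ranges were 0.911 to 0.912, 0.863 to 0.891 and 0.848 to 0.890, and without replicate 2 the last 2 were 0.891 and 0.869 to 0.890.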

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

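Thinned abundance, the voom fit and the alternatives for circRNAs seen in one group only, except the read minimum, were chosen after seeing the data. The called circRNAs kept their direction in each alternative, 59 of them where only those seen in all 6 libraries were tested and 64 otherwise (equal depth in the draw with the median number of calls). Since 63 of the 64 had groups that did not overlap, only settings that rescale or redraw the values could have turned their direction. The 64 calls became 27 with a pseudocount of 1.19 RPM, 42 when only circRNAs seen in all 6 libraries were tested, 0 in limma without intensity trend and robust variances (1408 at an unadjusted p under 0.05), 97 with voom on recovered reads, 41 at equal depth and 952 at an unadjusted p under 0.05 with at least 2-fold change. Leaving out 1 library gave 4 to 58 calls, and the cause of these changes was not tested. Counts under the other settings lay between 49 and 71. Equal summed RPM moved nothing. The median log2 fold change of all circRNAs tested was 0.18, and it was 0.02 after quantile normalization and 0.26 after median centring. The centring used only the circRNAs seen in all 6 libraries. The median was 0.28 without the filter, and 0.31 and 0.07 with the smaller and a larger pseudocount (19.1 RPM). Without normal pressure replicate 2 it was 0.06. With the replicate number as a block, 65 were called, 54 of them among the 64. Same-numbered libraries did not deviate together (correlations -0.002, -0.024 and 0.003, against -0.050 to 0.047 for different numbers). No shared effect of the number was seen, which does not settle whether equal numbers mark pairs. The difference in circRNAs detected was 6369, 3907 above 4 reads and 810 at equal depth. The 655 circRNAs seen in one group only became 274 at equal depth and 1139 to 1605 with 1 library left out. In hypobaric hypoxia only, 605 became 191 and 762 to 1522. In normal pressure only, 50 became 16 above 4 reads, 82.6 at equal depth and 83 to 377. The planned count-model tests on recovered reads were not run. Depth limits detection most in normal pressure replicate 2, where 2 reads are 13.2 RPM.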

Other observations

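All tests in this part were chosen after the result was seen, except the thinning of reads in couples and the correlation of neighbours within groups.

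The 10 most abundant circRNAs of a library held 7.81% ± 0.128 of the reads in normal pressure and 7.68% ± 0.124 in hypobaric hypoxia, the top 100 held 25.4% ± 0.731 and 24.9% ± 0.0796, and the top 1000 held 58.4% ± 1.95 and 57.1% ± 0.117 (SD, n = 3). These differences as deposited had p = 0.4, 0.3 and 0.1 (exact permutation test, two-sided). At equal depth the differences in these shares were 0.0073, -0.0352 and -0.133 percentage points (exact permutation test, two-sided, p = 1, 0.9 and 1). Normal pressure replicate 2 set much of this, since without it the differences in the shares of the top 100 and top 1000 were -0.0701 and -0.166 percentage points as deposited, and the 3 differences at equal depth turned to -0.0846, 0.136 and 0.391. The effective number of circRNAs, the exponential of the Shannon entropy, was 3235 ± 185 in normal pressure and 3331 ± 12.7 in hypobaric hypoxia at equal depth (SD, n = 3, exact permutation test, two-sided, p = 0.7), and without replicate 2 the order turned, with 3340 in normal pressure. As deposited the effective number was 3653 ± 546 in normal pressure and 4187 ± 30.6 in hypobaric hypoxia (SD, n = 3, exact permutation test, two-sided, p = 0.1). These tests cannot go below 0.1 and do not show that the groups were alike.

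More circRNAs were seen in hypobaric hypoxia only than in normal pressure only, 605 against 50. Depth in circRNA reads is a candidate explanation for part of this excess, since 19.5% of the difference was left at equal depth. Thinning takes away reads and would also shrink an excess not due to depth. The 19.5% therefore does not measure how much of the excess came from unequal depth. Whether the depth reflects deeper sequencing or a larger circRNA share of the RNA cannot be read from values scaled to one total. Depth as the whole explanation was argued against by pairs of libraries brought to 365070 reads without normal pressure replicate 2. There the lowest of 3 hypobaric hypoxia pairs had 1171 circRNAs absent from both normal pressure libraries and the highest of 12 mixed pairs 966. The normal pressure pair had 745 to 751, below the lowest mixed pair at 800. The 3 hypobaric hypoxia pairs share libraries and were set against the same 2 normal pressure libraries, so they are not independent. The shallow replicate 2 as the whole explanation was argued against by the same hypobaric hypoxia pairs, whose mean was 1.60 times that of the normal pressure pair. Thinning couples of reads together (10 draws), in case reads were counted in couples, left 1270 for the lowest hypobaric hypoxia pair against 988 for the highest mixed pair. This keeps more scarce circRNAs in the libraries that lose reads, mainly those of hypobaric hypoxia. It could therefore only raise the counts of hypobaric hypoxia pairs and cannot decide whether counting in couples made the excess. The 19.5% rests on reads thinned singly. What depth does not explain of the excess may come from the exposure, or from differences in RNA input, RNase R digestion or duplicate reads. These were not tested.

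The 64 called circRNAs were weighed against depth and chance. Thinning to equal depth left a median of 0.968 of their log2 fold changes (0.912 to 1.01 over 20 draws), with the direction kept in at least 63 of the 64. With fewer reads, 41 circRNAs were called in the draw with the median number of calls, 35 of them among the 64. Random thinning leaves the relative abundance of an abundant circRNA nearly unchanged on average, and the 64 were mostly abundant. Folds and directions were therefore largely set in advance, and thinning cannot decide whether depth played a part. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many calls, the real one with 64, and the highest of the others gave 3. 10 splits are too few for a share under 0.05. The exposure stays open as an explanation and was not tested apart from anything else that differed between the groups.

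Called circRNAs had called neighbours in ID number. Of the 64, 20 had another call of the same direction within 20 ID numbers, 9 of them higher and 11 lower. In comparison, 10000 draws matched on abundance gave 2.15 on average and 13 at most (permutation p = 0.0001, the smallest these draws can give). This argues against calls without relation to the ID number. The draws take circRNAs as independent, so deviations that neighbours share within groups could also bring calls together. Across 1057 pairs of consecutive IDs seen in all 6 libraries, log2 fold changes correlated at 0.17, above the highest of 1000 shuffles at 0.10. Reads divided between neighbouring junctions would make neighbours deviate in opposite directions. The mean correlation of neighbours within groups was 0.0689, against a mean of 0.0137 in random pairs (SD of that mean over 1000 draws 0.0156). On average, neighbours therefore did not deviate in opposite directions. A deviation shared by neighbours could hide divided reads in some pairs, so this does not decide whether reads were divided. If the IDs follow genome order, neighbours may share a host gene and change with it, which was not tested because the files give no coordinates.

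Read numbers did not decline evenly, since in each of the 6 libraries more circRNAs had 4 reads than 3 and more had 6 than 5, for example 1624 against 1540 and 1214 against 960 in normal pressure replicate 1.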
